A study of Homo sapiens with 12 samples.

How the data were processed

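Total RNA of 3 H358 derivatives was hybridised with parental H358 RNA on 12 Agilent dual-colour whole-genome arrays, labelled per the labels' protocols with the Agilent Low Input Quick Amp kit. Groups were taken from the labels: Control, Brg1i.1 and Brg1i.2, each with 4 technical arrays of 1 biological sample; whether the arrays of a library share 1 extract is not given in the sources used here. Per the file headers, the deposited scanner files hold the mean and background intensity of each spot in Cy3 and Cy5 on a linear scale, without normalization, from Agilent Feature Extraction 10.7.3.1. They also hold processed intensity values, which Feature Extraction corrected for background, detrended and normalized between dyes, per the file headers, and their log10 ratio of Cy5 over Cy3. The authors also deposited a value per spot and array in a series matrix, which, set against the scanner values, was a log2 ratio of Cy5 over Cy3 with a slope of 0.941 to 0.957 and r of 0.970 to 0.995 across spots. Its column medians were -0.00851, -0.0031, -0.00137 and -0.00534 in Control, 0.00107, -0.00303, -0.00506 and -0.00156 in Brg1i.1 and -0.00319, -0.00198, -0.00111 and -0.00303 in Brg1i.2. Its scale, direction and centring near 0 were thus read from the values, while the normalization behind it is not given in the sources used here. Probe positions are on hg18, as the files give them.

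The arrays held 43376 non-control spots of 41000 probes. Probes were named through their accession (23680), symbol (2802) or synonym (1128) in a RefSeq gene table; 13390 matched none and kept the name in the file. Mean signals were corrected with limma's normexp method (offset 50), normalized within each array by loess with control spots at weight 0, and averaged over the spots of a probe, leaving out spots that Feature Extraction marked as outliers (124 to 673 per array). Probes well above background in Cy3 on all 4 arrays of at least 1 library were kept (27981 probes), and a gene was read from its brightest probe, which left 20472 genes, 13629 of them with a RefSeq name. Of the called genes, 385 in Brg1i.1 and 504 in Brg1i.2 had over 1 probe; all probes had the same sign for 371 and 481 and all were called for 157 and 220. R 4.3.3, limma 3.58.1 and data.table (version 1.17.8) were used.

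Before the data were examined, the comparisons, the gene lists, the alternatives and the rule for named genes were fixed. The planned quantity was Cy3 over Cy5, since the labels put the line in Cy3. The values showed the library differences in Cy5, so every value is given as Cy5 over Cy3, the negative of the planned quantity, with the same tests. Genes were called in limma (lmFit and eBayes over all 12 arrays, 1 shared spread) at a Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold; the prior had 9.4 degrees of freedom. For the comparison of lines, each library's arrays were averaged and Brg1i.1 and Brg1i.2 were set as 2 replicates against Control as 1, with a prior of 3.53 degrees of freedom. Differences between the effects in Brg1i.1 and Brg1i.2 were also tested with limma's treat method against 2-fold. A probe not well above background on any array of a side got a bound from the normalized Cy5 levels: the bright side's mean against the dim side's mean of the higher of the lowest level among probes well above background and the dim probe's own. Bounds above the fold of the log ratio itself were not reported. The 29 gene lists were described by their calls, over all genes and adjusted over the list alone, and by the percentile of their median among 10000 random lists matched on intensity in 10 bins.

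Named genes were SMARCA4 and SMARCA2; the 10 per direction with the largest smaller difference among genes called alike in Brg1i.1 and Brg1i.2, with a value on all 12 arrays and arrays that did not overlap; the next 5 per direction in each of Brg1i.1 and Brg1i.2; up to 4 called members of each list; the 5 per direction with the largest difference between Brg1i.2 and Brg1i.1 and between Control and the common RNA; and the 3 per direction with the largest bound. Only genes with a proper symbol were eligible. In all, 130 genes were named this way, and some further members of these groups are not reported here.

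In each array 68.2% to 75.5% of spots were well above background in Cy3 and 70.8% to 76.9% in Cy5; median mean signals were 158.5 to 277.4 in Cy3 and 218.1 to 329.6 in Cy5, and 0 spots were saturated. Arrays of 1 library correlated with r of 0.970 to 0.981 across genes in Control, 0.883 to 0.943 in Brg1i.1 and 0.921 to 0.959 in Brg1i.2. The 12 arrays lay on 4 slides, each with 1 array of each library at a position that was the same for a library on every slide. The procedure was tested on simulated data with 50 genes changed at each size among 19789. The array-level test recovered 100% at log2 changes of 1.5, 2, 3 and 4 in both comparisons with Control, with 0 false calls. For the line-level test with a line spread drawn from limma's prior it recovered 60%, 96%, 94% and 100%, with 10 false calls. In another simulation, each line's spread was a normal draw scaled by the observed difference between Brg1i.1 and Brg1i.2 of a random gene. The line-level test then recovered 0% at each size, with 0 false calls. Such a spread has heavier tails than the observed differences, so the 0% is not the power of the test in these data.

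Alternatives were the background correction, the normalization, the processed signals, the series matrix, Cy3 alone, the filter on dim probes, the mean over probes, the thresholds, the replicate number or slide as a block, the parental RNA as a second line and leaving out each array. Cy5 alone, a filter on Cy5 and the common RNA in place of Control were added after the data were seen. No genome sequence was used here, and control spots were left out of all tests.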

Results

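Gene expression was measured in 3 derivatives of H358, a human non-small-cell lung cancer cell line, on 12 dual-colour oligonucleotide arrays. The derivatives were labelled Control, Brg1i.1 and Brg1i.2, and the names refer to short hairpin RNAs, a control and a pair against BRG1. BRG1 is the product of SMARCA4, an ATPase that drives the SWI/SNF chromatin remodelling complex. Each derivative was 1 biological sample measured on 4 technical arrays, each time against RNA of the parental H358 cells in the other dye. Control and Brg1i.1 were kept in G418 and Brg1i.2 in puromycin, so the selection drug differed between Brg1i.2 and the other two. Between 68.2% and 75.5% of spots were well above background in Cy3 and between 70.8% and 76.9% in Cy5, and 0 spots were saturated. Signal over background and the number of arrays limited the precision, and the p-values over arrays measured technical spread only. The comparisons asked which genes differed when BRG1 was depleted, whether both hairpins gave the same genes, and how the control line stood against the parental cells.

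SMARCA4, the targeted gene, was lowest in the library labelled Control. Its log2 ratio of Cy5 over Cy3 was -2.43 ± 0.091 there, -1.61 ± 0.10 in Brg1i.1 and -0.12 ± 0.02 in Brg1i.2 (mean ± SD, n = 4 arrays each), or 0.185, 0.327 and 0.921 times the Cy3 level. The library labelled Brg1i.2 was thus 4.97-fold above the one labelled Control (log2 difference 2.31, SE 0.065, limma adjusted p = 2.52e-16). Brg1i.1 was 1.76-fold above it (log2 difference 0.82, limma adjusted p = 2.09e-09), which fell short of the 2-fold threshold. These values came from probe A_23_P39034 (hg18, chromosome 19, 11033673 to 11033732); A_23_P39040 (11030037 to 11030520) and A_24_P212851 (10999475 to 10999534) gave the same order of the 3 libraries. Within the 4 slides, each of which held 1 array of each library, the differences from Control were 0.65 to 0.883 in Brg1i.1 and 2.24 to 2.44 in Brg1i.2. With each line as 1 replicate, limma's adjusted p for SMARCA4 was 0.202.

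The dyes in the labels were contradicted by the intensities, and this sets the sign of every value. The labels put each line in Cy3 and the parental RNA in Cy5. Between the libraries labelled Control and Brg1i.2, however, 70 genes differed by at least 2-fold in the processed Cy3 signal and 3135 in Cy5. For Brg1i.1 against Control the numbers were 52 and 2590. These counts came from limma at an adjusted p under 0.05 with the slide as a block. The numbers given below for Cy3 alone and Cy5 alone had no block and are slightly smaller. The mean SMARCA4 signal was 34490, 30190 and 30380 in Cy3 and 6664, 10200 and 29130 in Cy5 in Control, Brg1i.1 and Brg1i.2. All values are therefore log2 of Cy5 over Cy3, read as a library over a common Cy3 RNA, a direction chosen after the data were seen and opposite to the labels. With the dyes as labelled, every sign turns, the numbers of higher and lower genes exchange, and SMARCA4 would be lower in Brg1i.1 and Brg1i.2 than in Control, with Control above the parental cells. Since SMARCA4 goes against the library labels in the direction used here, Control, Brg1i.1 and Brg1i.2 mean only the libraries that carry these labels.

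**Figure D1:**
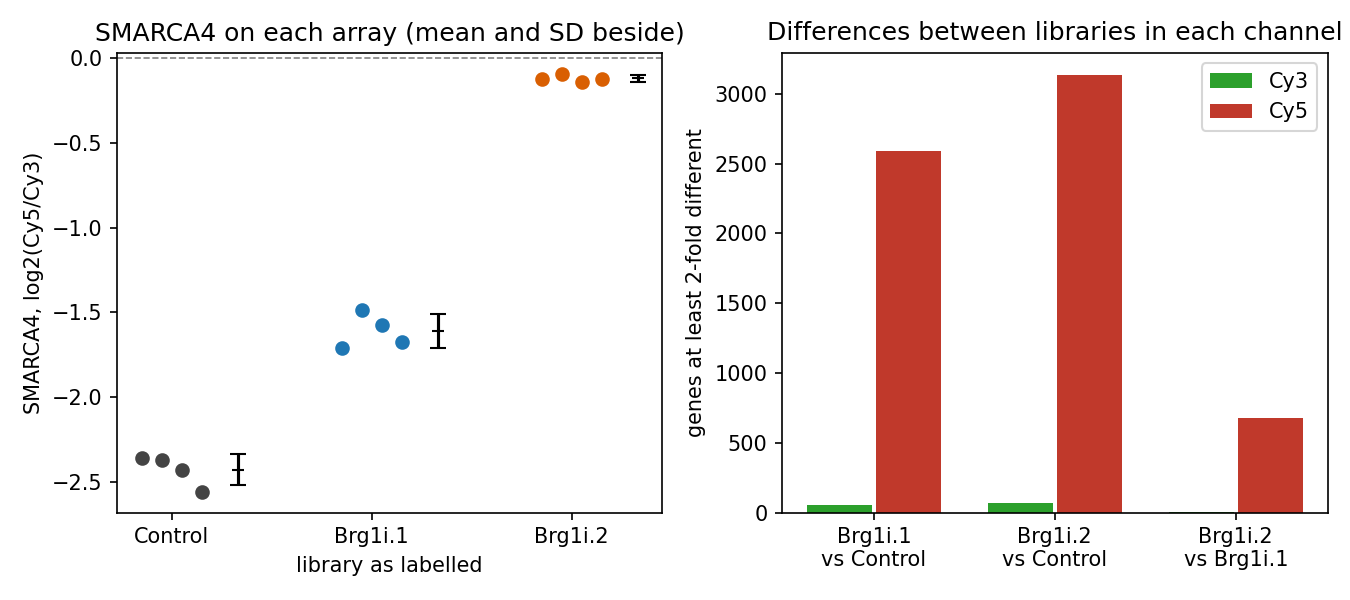
Left, log2 of Cy5 over Cy3 for SMARCA4, 1 point per array by labelled library with mean and SD beside (n = 4 arrays), lowest in Control at -2.43 and highest in Brg1i.2 at -0.12. Right, bars of the number of genes at least 2-fold different between libraries in the processed signal of each channel (limma with the slide as a block), at most 70 in Cy3 and up to 3135 in Cy5.

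FGF13, an intracellular member of the fibroblast growth factor family, stood 65.7-fold and 96.1-fold higher in Brg1i.1 and Brg1i.2 than in the library labelled Control, the largest rise shared by both when ranked by the smaller difference. All ranks given here and below were taken over genes with a proper symbol that were well above background on at least 1 array of each side, and those of shared genes over the ones with a value on all 12 arrays. SLAMF7, a receptor of immune cells, rose 25.1-fold and 26.9-fold, AIM2, a sensor of cytosolic DNA, rose 14.2-fold and 37.8-fold, and NKX2-1, the transcription factor of lung epithelium, rose 10.3-fold and 11.7-fold. In the opposite direction DLC1, a GTPase-activating protein, was 116-fold and 61.6-fold lower, and TCEAL9 was 40.9-fold and 35.9-fold lower. The log2 ratio of FGF13 was -6.94 ± 0.078, -0.90 ± 0.076 and -0.35 ± 0.038 in Control, Brg1i.1 and Brg1i.2, and that of DLC1 was 6.01 ± 0.10, -0.86 ± 0.056 and 0.061 ± 0.20 (mean ± SD, n = 4 arrays). Relative to Control, the genes that rose moved in the direction of SMARCA4 and those that fell against it, whichever way the dyes are read.

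Among the other genes with the largest shared rises, with the log2 difference from Control in Brg1i.1 and then in Brg1i.2, were DAPP1 (3.76 and 4.04), TCIM (3.68 and 4.32), LIMCH1 (3.67 and 3.88), CEMIP (3.40 and 3.88), KCNK1 (3.37 and 3.39) and ZBED2 (3.30 and 3.64). Among such genes the largest shared falls after DLC1 and TCEAL9 were in PODXL (-4.28 and -4.87), which encodes the sialomucin podocalyxin, SALL2 (-4.26 and -4.43), PREX1 (-4.21 and -4.09), CRH (-3.88 and -4.20), the corticotropin-releasing hormone, BEX2 (-4.47 and -3.63), ZNF219 (-3.43 and -4.73), PLAC8 (-3.41 and -3.66) and EPB41L2 (-3.36 and -3.52). A second probe of NKX2-1 gave 1.49 and 1.64 and one of LIMCH1 gave 2.33 and 2.26, in the same direction but smaller. Several genes were not well above background on any array of 1 side. LEF1, a transcription factor of Wnt signalling, was at least 56.3-fold and 57.5-fold higher in Control than in Brg1i.1 and Brg1i.2, by normalized Cy5 levels that are open to dye bias (limma adjusted p = 5.35e-20 and 2.38e-20). SORBS2 and TCEAL7 were also dim in Brg1i.1 and Brg1i.2 and lower there. RARB, the retinoic acid receptor beta (limma adjusted p = 4.36e-16 and 9.59e-14), MCTP2 and CRYGC were dim in Control and higher in Brg1i.1 and Brg1i.2. For these 5 genes no bound is given, because the one from Cy5 levels was larger than the difference in the log2 ratio. A second probe of MCTP2 gave 0.708 and 0.809.

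In all, 1475 genes differed by at least 2-fold between Brg1i.1 and Control (714 higher, 761 lower) and 1965 between Brg1i.2 and Control (889 higher, 1076 lower), of 20472 tested with limma at an adjusted p under 0.05. The arrays of Brg1i.1 and Control did not overlap for 52.2% of genes and those of Brg1i.2 and Control for 58.4%, where chance gives 2.86%. Both libraries called 1210 genes in the same direction, 560 higher and 650 lower, and 1 in opposite directions, MAF. Independent lists of these sizes would share 71, and unchanged libraries simulated against the same Control arrays shared 0 in 50 runs. The log2 differences correlated across genes with r = 0.889, against 0.501 in the simulation, and their covariance was 0.338 against 0.00303; genes are not independent replicates. With the Control arrays split into 2 and 2 so that no array was shared, r was 0.863 to 0.879, the covariance 0.333 to 0.337 and the shared calls 1185 to 1210 over 6 splits. All Control arrays came from 1 sample, so the split and the simulation cover noise between arrays and leave the Control line itself shared by both comparisons. Within the 4 slides, 1493 to 1597 genes of Brg1i.1 and 1934 to 2024 of Brg1i.2 differed by at least 2-fold, 1172 to 1275 in the same direction in both, and 100% of the calls had the same sign on every slide. The calls were made at 2-fold on these same arrays, so the shared sign is no separate support for them. With the slide as a block, 1474, 1966 and 1209 genes were called in Brg1i.1, in Brg1i.2 and in both. In Cy3 alone the calls fell to 49 and 65, all lower, and with Agilent's processed signals they came to 2467 and 2994.

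**Figure D2:**
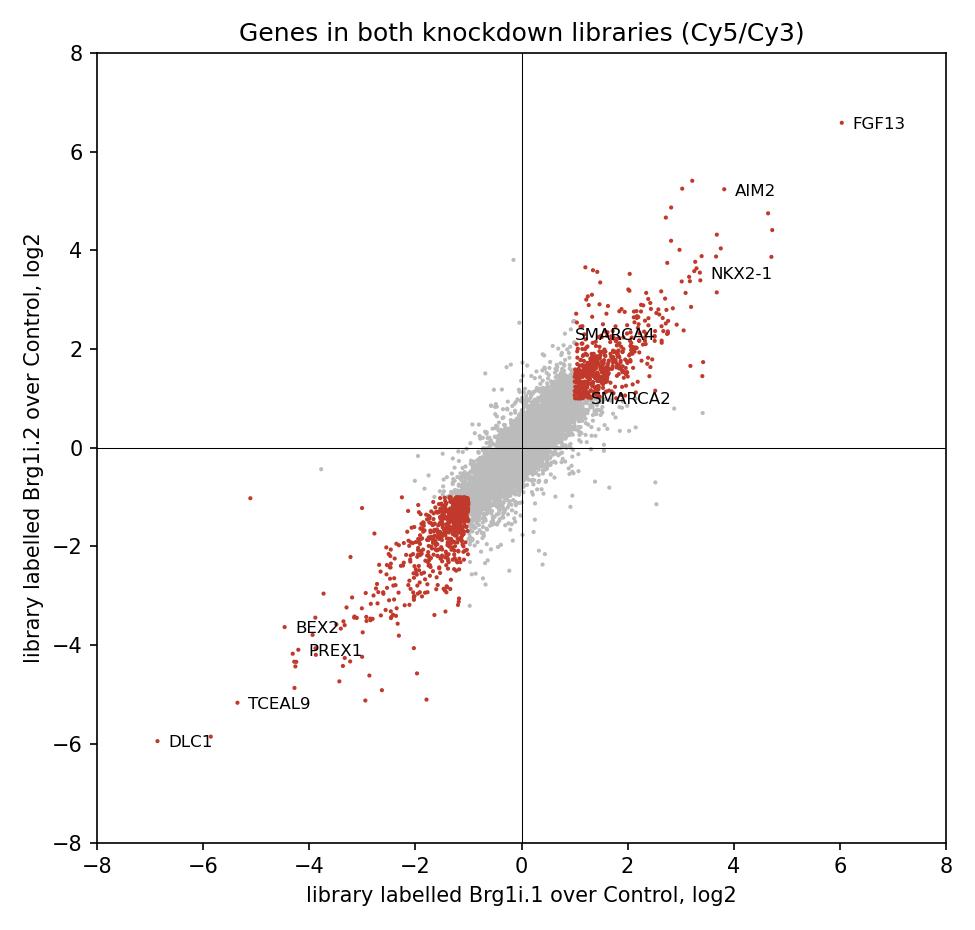
Log2 difference from the library labelled Control in Brg1i.1 (x axis) and in Brg1i.2 (y axis), 1 point per tested gene, with the 1210 genes called in the same direction in both in red and all others in grey. The differences correlate across 20472 genes with r = 0.889, and SMARCA4 lies at 0.82 and 2.31.

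With each line taken as 1 replicate, FGF13 (limma adjusted p = 0.0104), SLAMF7 (0.00909) and NKX2-1 (0.0113) were higher and DLC1 (0.0142), TCEAL9 (0.00909) and PODXL (0.0142) lower in the mean of Brg1i.1 and Brg1i.2 than in Control. These 6 genes were picked for large differences in the same direction in both libraries, and the distance between these gives the test its only spread, so the p-values are not free of that choice. In simulations, each line's spread was a normal draw scaled by the observed difference between Brg1i.1 and Brg1i.2 of a random gene. There this test recovered 0% of the changed genes at each size. Such a spread has heavier tails than the observed differences, and the test called 1467 genes in the real data. The 0% is therefore not its power here. SMARCA2, which encodes BRM, the alternative ATPase of SWI/SNF, was higher in both (1.11 and 1.01; line-level adjusted p = 0.0354), with a log2 ratio of -1.44 ± 0.038 in Control, -0.33 ± 0.10 in Brg1i.1 and -0.43 ± 0.11 in Brg1i.2 (probe A_23_P60354, hg18, chromosome 9, 2182841 to 2182900, n = 4 arrays). Its call in Brg1i.2 at the 2-fold threshold was lost without Control replicate 3 (0.997), Brg1i.2 replicate 1 (0.99) or Brg1i.2 replicate 3 (0.98), and with no background correction (0.93), median centring (0.92) or the authors' values (0.996). Limma called 1467 genes at the line level, 648 higher and 819 lower, of which 1152 differed by at least 2-fold. This comparison assumes that the single Control line varied like the other two. Where the common RNA was added as a second line beside Control, limma called 0 genes (867 at an unadjusted p under 0.05), without Brg1i.1 replicate 1 it called 936, with no background correction 966, with no filter on dim probes 104, and with Agilent's processed signals 578, of which 345 were higher.

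Brg1i.1 differed most from Control, outside the shared genes named above, in DNAH2 (3.68 and 3.15), a dynein heavy chain, AMY1C (3.42 and 1.74), CAPS (3.42 and 0.70), LCK (3.28 and 3.77), a tyrosine kinase of lymphocytes, and FOXC1 (3.26 and 3.58), all higher in Brg1i.1. The largest falls in Brg1i.1 by the same rule were in TFPI2, a serine protease inhibitor (-3.89 and -3.44), IL13RA2 (-3.73 and -2.96), CCK (-3.49 and -3.58), SEC14L4 (-3.33 and -3.59) and ASRGL1 (-3.33 and -4.26). The pairs give Brg1i.1 and then Brg1i.2, and only the value of CAPS in Brg1i.2 was not called, being below the 2-fold threshold. TFPI2 and CCK each lacked a value on 1 array of Brg1i.1, and SEC14L4 was well above background on 2 of 4 arrays of Brg1i.2. FOXC1 rested on probes that disagreed, since the others gave 2.38 and 2.76, and 0.15 and 0.36, and the 4 probes of ASRGL1 ran from -2.92 to -4.07 in Brg1i.1.

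For Brg1i.2 the largest rises outside the genes named above were in SPANXB1, SPANXA1 and SPANXD (5.41, 5.25 and 4.87), testis antigens of 1 near-identical family whose probes cannot be assigned to single members, and in ANGPTL2 (4.67) and HPGD (4.01), the enzyme that inactivates prostaglandins. The largest falls outside those genes were in PRAME, a cancer-testis antigen (-5.12), ACAA2, a thiolase of mitochondrial fatty acid oxidation (-5.10), TTC7B (-4.91), PNMA2 (-4.62) and ARHGEF40 (-4.57). Each of these 10 genes was also called in the same direction in Brg1i.1, with log2 differences of 3.22, 3.03, 2.82, 2.72, 2.98, -2.94, -1.79, -2.63, -2.87 and -1.97 in that order. PRAME was well above background on 3 of 4 arrays of Brg1i.2. Second probes gave smaller values in Brg1i.2 for ANGPTL2 (2.87), HPGD (2.67) and PRAME (-2.7).

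The gene lists were compared with Control in both libraries. The number of genes given for a list counts the members tested, which needed a probe that passed the filter on Cy3. For every list in the next paragraphs, the numbers of genes adjusted over the list alone equalled those over all genes. Pairs of values give the log2 difference in Brg1i.1 and then in Brg1i.2, with a median array SD per gene of 0.0951, 0.103 and 0.088 in Control, Brg1i.1 and Brg1i.2 and n = 4 arrays each. Percentiles place a list's median among those of 10000 random lists of the same size matched on intensity. Over all 20472 genes, 13307 in Brg1i.1 and 13937 in Brg1i.2 differed from Control at an unadjusted p under 0.05 in limma, in either direction. With the slide as a block no list median moved by more than 0.017. Each slide held 1 array of each library, so a block could move a median only through missing values, and this is no test of slide effects. Members given without a value lay outside the rule for named genes and were named after their values were seen. The library labelled Control stood apart from the common RNA in many lists, and numbers or medians against that RNA are given for these. Some genes were well above background on only part of a library's arrays: CXCL8 on 3 of 4 in Control and in Brg1i.1, TEK on 1 of 4 in Control, HLA-DPB1 on 3 of 4 in Brg1i.1 and ABCA3 on 3 of 4 in Brg1i.2.

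Epithelial genes had the largest median of the 29 lists, above Control in both libraries, as was SMARCA4. Between Brg1i.2 and Brg1i.1, where SMARCA4 differed by 1.49, the epithelial median was -0.016 (percentile 42.3). Of 32 epithelial genes, 15 rose and none fell in Brg1i.1, and 17 rose and 2 fell in Brg1i.2. OVOL2 (2.66 and 2.63), a transcription factor of epithelial cells, EPCAM (2.15 and 2.03), the epithelial cell adhesion molecule, GRHL2 (2.10 and 1.62), a regulator of epithelial junction genes, and KRT19 (1.74 and 1.94), a keratin, rose in both, while the tight junction genes CLDN3 and OCLN fell in Brg1i.2. The list's medians were 0.94 and 1.12 (percentiles 100 and 100), and 0.88 to 1.12 and 0.99 to 1.19 within the slides. Against the common RNA 20 epithelial genes were lower in Control, 2 in Brg1i.1 and 3 in Brg1i.2, with medians of -1.56, -0.41 and -0.41. Of 24 mesenchymal genes, 2 rose and 5 fell in Brg1i.1, and 2 rose and 5 fell in Brg1i.2. CCN2, a matricellular growth factor (-2.03 and -3.08), CCN1 (-1.27 and -2.46) and GNG11 (-3.01 and -1.22) fell and CDH11, a cadherin of mesenchymal cells (2.33 and 2.24), rose, as did SNAI1; AXL fell in both, LOX in Brg1i.1 and SPARC in Brg1i.2. Mesenchymal genes had medians of -0.041 and -0.016, which lay on both sides of 0 across the slides, and against the common RNA 9, 6 and 6 of them were higher in Control, Brg1i.1 and Brg1i.2. All 32 epithelial genes were tested, but only 24 of 28 mesenchymal and 24 of 31 lung lineage genes. Members without a probe that passed the filter on Cy3, such as those dark in the common RNA, do not enter these medians, whatever their level in a library. Of 24 genes of lung epithelial lineages, 3 rose and 1 fell in Brg1i.1, and 4 rose and 1 fell in Brg1i.2. Besides NKX2-1, HOPX, expressed in alveolar cells (2.33 and 2.58), and TP63, a factor of basal cells (1.40 and 2.06), rose and ABCA3, the surfactant lipid transporter (-1.91 and -1.95), fell, and FOXA1 rose in Brg1i.2. Another TP63 probe gave 0.229 and 0.42, and the probes' mean ended its call in Brg1i.1 (0.82). The medians of this list were 0.067 and 0.11 (percentiles 80.2 and 89.7); 7, 5 and 4 members lay below the common RNA in Control, Brg1i.1 and Brg1i.2.

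**Figure D3:**
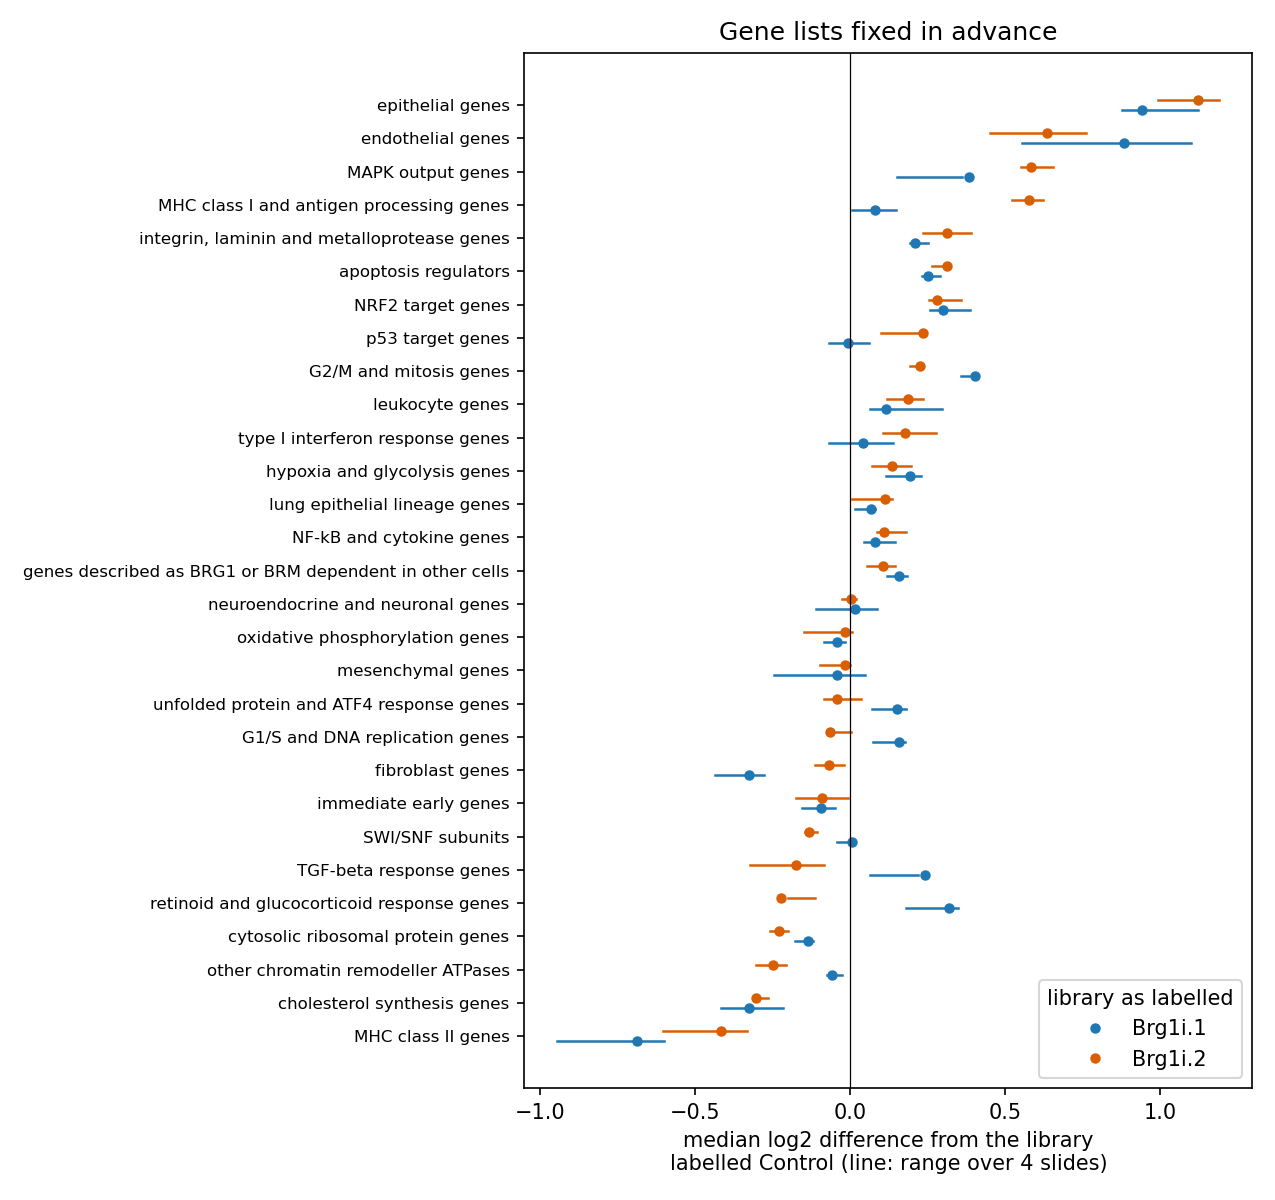
Median log2 difference from the library labelled Control for each of the 29 gene lists in Brg1i.1 and Brg1i.2, with a line for the range of the medians within the 4 slides. Epithelial genes lie furthest from 0, at 0.94 in Brg1i.1 and 1.12 in Brg1i.2.

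Among SWI/SNF subunits, SMARCD3, an accessory subunit (-2.02 and -3.01), and DPF3, a histone reader (-1.62 and -1.21), fell in both libraries and SMARCA2 rose in both, whereas SMARCA4 passed in Brg1i.2 alone. Among 29 subunits, 1 rose and 2 fell in Brg1i.1, and 2 rose and 3 fell in Brg1i.2, where BCL11A fell too; medians were 0.0074 and -0.13, with a mean of opposite sign in Brg1i.1 (-0.075). Of 19 ATPases of other chromatin remodellers, limma called 0 (9 at an unadjusted p under 0.05) in Brg1i.1, and 1 fell and none rose in Brg1i.2, that of SMARCA1 (-0.99 and -1.55). SMARCA1 also passed in Brg1i.1 without Control replicate 2 (-1.003) or Brg1i.1 replicate 1 (-1.06). The medians of those ATPases were -0.060 and -0.25 (percentiles 23.6 and 2.06), and -0.30 to -0.21 within the slides in Brg1i.2. Of 20 genes described as dependent on BRG1 or BRM in other cells, 3 rose and 1 fell in Brg1i.1, and 3 rose and 3 fell in Brg1i.2. SYK, a tyrosine kinase of immune receptors (1.54 and 2.5), KRT8, an epithelial keratin (1.16 and 1.30), and CXCL8, the neutrophil chemokine (1.05 and 1.83), rose in both; SPARC and MYC fell in Brg1i.2 and CYP1A1 in Brg1i.1. The medians of this list were 0.16 and 0.11, and those within the slides 0.12 to 0.18 and 0.054 to 0.14. CXCL8 lost its call in Brg1i.1 without Control replicate 1 (0.94), 2 (0.92) or 4 (0.94) or Brg1i.1 replicate 1 (0.73), and with no background correction (0.97).

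Markers of other cell types moved in part, among the members tested. These were 10 of 21 neuroendocrine and neuronal, 8 of 15 fibroblast, 11 of 16 leukocyte and 6 of 12 endothelial genes. The filter on Cy3 left out markers that were dark in the common RNA, whatever their level in a library. Of 10 neuroendocrine and neuronal genes, 4 fell and none rose in Brg1i.1, and 3 fell and none rose in Brg1i.2. NEFM, a neurofilament subunit (-1.60 and -1.65), DDC, an enzyme of dopamine and serotonin synthesis (-1.54 and -1.70), and SCG2, a secretory granule protein (-1.95 and -1.16), fell in both, and ENO2 (-1.26 and -0.67) in Brg1i.1. A second NEFM probe gave 0.174 and 0.256, and the mean of its probes ended both calls (-0.71 and -0.70). The medians (0.014 and 0.0012) and means (-0.49 and -0.29) of these genes differed in sign. Of 8 fibroblast genes, 1 rose and 1 fell in Brg1i.1, and 2 fell and none rose in Brg1i.2, with medians of -0.33 and -0.069 (-0.44 to -0.28 and -0.11 to -0.020 within the slides). The fall of FBLN1 (-1.2 and -2.09) in Brg1i.1 ended with the mean of its probes (-0.70), the other probe being at -0.198 and -0.637; COL1A1 (-0.91 and -1.29) fell in Brg1i.2 and FAP (1.18 and 0.68) rose in Brg1i.1. Of 11 leukocyte genes, 1 rose and none fell in Brg1i.1, and 1 rose and none fell in Brg1i.2, namely LAPTM5, a lysosomal protein of blood cells (2.06 and 2.34); the list's medians were 0.11 and 0.19, and 0.063 to 0.30 and 0.12 to 0.23 within the slides. Of 6 endothelial genes, 2 rose and none fell in Brg1i.1, and 1 rose and none fell in Brg1i.2, with medians of 0.88 and 0.64 (percentiles 100 and 100), and 0.55 to 1.10 and 0.45 to 0.76 within the slides. ENG (1.53 and 0.83) and PECAM1 (1.005 and 0.44) passed in Brg1i.1 and TEK (0.998 and 1.05) in Brg1i.2. Of these, PECAM1 lost its call without Control replicate 1 (0.96) or 4 (0.99) or Brg1i.1 replicate 2 (0.97), 3 (0.99) or 4 (0.99). TEK passed in Brg1i.1 without Control replicate 1 (1.005) or 3 (1.04) or Brg1i.1 replicate 2 (1.04) or 3 (1.04), and not in Brg1i.2 with no background correction (0.86).

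Cell cycle genes differed from Control by less than 2-fold with 1 exception, TYMS, the thymidylate synthase (-0.73 and -1.25), which fell in Brg1i.2. Of 32 G2/M and mitosis genes, limma called 0 (26 at an unadjusted p under 0.05) in Brg1i.1, and limma called 0 (27 at an unadjusted p under 0.05) in Brg1i.2, although their medians of 0.40 and 0.22 stood at percentiles 100 and 99.7 and were 0.36 to 0.41 and 0.19 to 0.24 within the slides. Of 32 G1/S and replication genes, limma called 0 (23 at an unadjusted p under 0.05) in Brg1i.1, and 1 fell and none rose in Brg1i.2; their medians were 0.16 and -0.064, that of Brg1i.2 on both sides of 0 across the slides. Of 26 p53 target genes, 1 rose and 1 fell in Brg1i.1, and 4 rose and 2 fell in Brg1i.2, with medians of -0.0059 and 0.23; the first had a mean of opposite sign (0.0017) and changed sign between slides, and the second was 0.10 to 0.22 within the slides. TP53INP1 (-1.67 and -2.5) fell and PHLDA3 (1.25 and 1.35) rose in both, and the death receptor gene FAS (0.68 and 1.37), PMAIP1 (0.81 and 1.09) and TNFRSF10C rose and RRM2B fell in Brg1i.2. Of 31 apoptosis regulators, 3 rose and 1 fell in Brg1i.1, and 6 rose and 2 fell in Brg1i.2, with medians of 0.25 and 0.31 (percentiles 99.8 and 100; 0.23 to 0.29 and 0.26 to 0.31 within the slides). BIK, which promotes apoptosis (2.85 and 2.83), the inflammatory caspase gene CASP1 (1.35 and 3.60) and the executioner caspase gene CASP6 (1.31 and 1.56) rose and BIRC3, an inhibitor of apoptosis (-1.42 and -1.12), fell in both, and BAK1 rose and BMF fell in Brg1i.2. Against the common RNA 6 apoptosis regulators were lower and 1 higher in Control.

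Interferon response genes lay below the common RNA in all 3 libraries. Of 38 interferon response genes, 2 rose and 2 fell in Brg1i.1, and 2 rose and 3 fell in Brg1i.2; IFIT1 (-1.13 and -1.89), MX1 (-1.45 and -1.38) and, in Brg1i.2, IFIT2 fell, and SAMD9L (1.32 and 1.49) and MX2 (1.07 and 1.43) rose. The call of MX2 in Brg1i.1 ended with the mean of its probes (0.79). Medians against Control were 0.041 and 0.18, the first on both sides of 0 across the slides and the second 0.11 to 0.28 within them. Against the common RNA, 24 were lower in Control, 19 in Brg1i.1 and 21 in Brg1i.2 and none higher, with medians of -1.12, -0.95 and -1.05, each at percentile 0. These medians share the same common RNA and are not separate observations. Of 26 NF-kB and cytokine genes, 1 rose and 1 fell in Brg1i.1, and 5 rose and 1 fell in Brg1i.2, with medians of 0.081 and 0.11 (0.046 to 0.14 and 0.087 to 0.18 within the slides). CXCL8 rose and BIRC3 fell in both, as given above, and IL1B, the interleukin 1 beta gene (0.79 and 2.08), the adhesion molecule gene ICAM1 (0.80 and 1.56), CSF2 and IER3 rose in Brg1i.2. Of 17 MHC class I and antigen processing genes, limma called 0 (5 at an unadjusted p under 0.05) in Brg1i.1, and 2 rose and none fell in Brg1i.2, the immunoproteasome genes PSMB8 (0.62 and 1.12) and PSMB9 (0.15 and 1.13). The median of that list was 0.079 in Brg1i.1 and 0.58 in Brg1i.2 (percentile 100; 0.52 to 0.62 within the slides). Of 11 MHC class II genes, 1 rose and 4 fell in Brg1i.1, and 1 rose and 3 fell in Brg1i.2, with medians of -0.69 and -0.42 (percentiles 0.06 and 2.09; -0.94 to -0.60 and -0.60 to -0.33 within the slides). HLA-DPA1 (-3.30 and -3.24), HLA-DPB1 (-2.46 and -2.35) and HLA-DMB (-2.31 and -1.97) fell in both, HLA-DRB5 fell in Brg1i.1, and CTSS, the protease cathepsin S (2.63 and 3.17), rose in both. Against the common RNA 5 MHC class II genes were higher in Control, and limma called 0 higher in Brg1i.1 and Brg1i.2 (9 and 10 at an unadjusted p under 0.05 in either direction).

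MAPK output genes lay above Control in both libraries by their medians of 0.38 and 0.58 (percentiles 100 and 100; 0.15 to 0.36 and 0.55 to 0.65 within the slides). Of 23 MAPK output genes, 3 rose and 2 fell in Brg1i.1, and 7 rose and 2 fell in Brg1i.2. The receptor gene EPHA4 (1.61 and 2.27), the EGFR ligand gene AREG (1.5 and 2.27) and TGFA rose in both and HBEGF fell in both; DUSP4 (0.92 and 1.48), EREG (0.90 and 1.41), DUSP6 and IER3 rose and MYC fell in Brg1i.2, and SPRY4 fell in Brg1i.1. Against the common RNA 8 of these genes were lower in Control, 4 in Brg1i.1 and 0 in Brg1i.2 (22 at an unadjusted p under 0.05 in limma). Of 20 immediate early genes, 1 rose and 3 fell in Brg1i.1, and 3 fell and none rose in Brg1i.2; besides CCN1, the nuclear receptor genes NR4A3 (-1.56 and -1.14) and NR4A1 (-1.15 and -1.28) fell in both and JUNB (1.24 and 0.90) rose in Brg1i.1, and the medians were -0.095 and -0.092 (-0.15 to -0.050 and -0.17 to -0.0061 within the slides). Of 23 TGF-beta response genes, 6 rose and 4 fell in Brg1i.1, and 4 rose and 5 fell in Brg1i.2. BAMBI, a decoy receptor (-3.19 and -3.03), CCN2 and IGFBP3 fell in both and INHBA, an activin subunit (1.2 and 3.66), IGFBP7 and LTBP3 rose in both; ID1 and SMAD7 rose and CDKN2B fell in Brg1i.1, and TGFB2 fell in Brg1i.2. Their medians were 0.24 and -0.18 (0.064 to 0.22 and -0.32 to -0.084 within the slides), with a mean of opposite sign in Brg1i.1 (-0.049); against the common RNA 7, 5 and 3 of them were higher in Control, Brg1i.1 and Brg1i.2. Of 30 integrin, laminin and metalloprotease genes, 6 rose and 1 fell in Brg1i.1, and 7 rose and 1 fell in Brg1i.2, with medians of 0.21 and 0.31 (percentiles 99.6 and 100; 0.19 to 0.25 and 0.23 to 0.39 within the slides). Of these, 9 were lower and 3 higher than the common RNA in Control, against 1 lower in Brg1i.1 and 1 in Brg1i.2, with medians of -0.38, -0.091 and 0.12. The metalloprotease genes MMP7 (2.35 and 3.14), MMP1 (1.84 and 2.23) and MMP13 and the laminin gene LAMA3 (2.43 and 2.94) rose in both, LAMA4 rose in Brg1i.1, ITGA6 and LAMB3 rose in Brg1i.2 and ITGB3 fell in both; 2 further LAMA3 probes gave 1.19 and 1.67, and 1.57 and 2.22. Of 20 retinoid and glucocorticoid response genes, 5 rose and 1 fell in Brg1i.1, and 6 rose and 2 fell in Brg1i.2. RARB, as given above, ALDH1A3, an enzyme of retinoic acid synthesis (1.72 and 1.80), CRABP2 and TGM2 rose in both, ANGPTL4 fell in both, and PLAAT4 rose and CYP26A1 fell in Brg1i.2; a second ALDH1A3 probe gave 0.943 and 0.766. The medians of the retinoid list were 0.32 and -0.22 (0.18 to 0.35 and -0.20 to -0.11 within the slides), the latter with a mean of opposite sign (0.21).

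Cholesterol synthesis genes lay below Control in both libraries, with medians of -0.33 and -0.31 (percentiles 0 and 0.04; -0.42 to -0.22 and -0.31 to -0.27 within the slides). Control was the library that stood apart, since the medians against the common RNA were 0.35, 0.076 and 0.064 in Control, Brg1i.1 and Brg1i.2. Of 25 cholesterol synthesis genes, 2 fell and none rose in Brg1i.1, and 1 rose and 2 fell in Brg1i.2; the sterol reductase gene TM7SF2 (-2.02 and -1.61) and LSS, the lanosterol synthase (-1.35 and -1.48), fell in both. Of 24 NRF2 target genes, 4 rose and 2 fell in Brg1i.1, and 4 rose and 1 fell in Brg1i.2, with medians of 0.30 and 0.28 (percentiles 99.9 and 99.8; 0.26 to 0.39 and 0.25 to 0.36 within the slides). Here too Control stood apart, with 6, 2 and 2 genes lower than the common RNA in Control, Brg1i.1 and Brg1i.2, 1 higher in each, and medians of -0.47, -0.078 and -0.022. GCLM, a subunit of the enzyme that starts glutathione synthesis (1.59 and 1.48), the malic enzyme gene ME1 (1.31 and 1.53) and AKR1B10 rose and the transporter gene ABCC3 (-1.59 and -2.07) fell in both, and SLC7A11 (0.87 and 1.38) rose in Brg1i.2. AKR1C1 (-2.01 and -0.67) fell in Brg1i.1, but its 4 probes ran from -2.01 to 0.0081 there. Of 30 genes of the unfolded protein and ATF4 responses, 2 rose and none fell in Brg1i.1, and 1 rose and 1 fell in Brg1i.2: STC2 (1.19 and 0.95) and VLDLR (1.30 and 0.82) rose in Brg1i.1, and SLC7A11 rose and ASNS, the asparagine synthetase (-0.79 and -1.26), fell in Brg1i.2. The mean of the ASNS probes ended that call (-0.72; a second probe gave -0.0879 and -0.183), and this list's medians were 0.15 and -0.042, the second on both sides of 0 across the slides and opposite to its mean (0.027). Of 31 hypoxia and glycolysis genes, 1 rose and 5 fell in Brg1i.1, and 1 rose and 2 fell in Brg1i.2; the peptide hormone gene ADM (-2.04 and -2.15) and ANGPTL4, an inhibitor of lipoprotein lipase (-1.5 and -2.30), fell in both, CA9 (-1.54 and -0.88), ENO2 and SLC2A3 fell and EGLN3 rose in Brg1i.1, and PDK1 rose in Brg1i.2. Medians of the hypoxia list (0.19 and 0.14; 0.12 to 0.23 and 0.070 to 0.20 within the slides) and its means (-0.040 and -0.023) differed in sign. Of 42 cytosolic ribosomal protein genes, limma called 0 (22 at an unadjusted p under 0.05) in Brg1i.1, and limma called 0 (26 at an unadjusted p under 0.05) in Brg1i.2, with medians of -0.14 and -0.23 (percentiles 0.53 and 0.01; -0.18 to -0.12 and -0.26 to -0.20 within the slides), and 0.26, 0.058 and 0.031 against the common RNA in Control, Brg1i.1 and Brg1i.2. Of 31 oxidative phosphorylation genes, 1 fell and none rose in Brg1i.1, and 1 fell and none rose in Brg1i.2, in each case UQCRC2, a core subunit of complex III (-1.21 and -1.92), and the medians were -0.043 and -0.016.

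Medians of several lists were close enough to 0 to change sign with another normalization, channel, filter or choice of probes and carry no direction: the neuroendocrine and oxidative phosphorylation lists in both libraries, p53 targets, interferon genes and other remodellers in Brg1i.1, and the G1/S, immediate early, ATF4, mesenchymal and TGF-beta lists in Brg1i.2. Those of SWI/SNF subunits in Brg1i.1 and of fibroblast genes in Brg1i.2 changed sign with 1 array left out. Further medians against the common RNA, in Control, Brg1i.1 and Brg1i.2, were -0.23, 0.084 and -0.13 for G2/M, -0.44, -0.079 and 0.033 for apoptosis, -0.49, -0.23 and 0.16 for MAPK output, 0.25, -0.022 and -0.014 for immediate early and -0.25, 0.10 and 0.035 for hypoxia genes. They were -0.33, -0.32 and 0.23 for MHC class I, 0.96, 0.11 and 0.23 for MHC class II, 0.57, 0.35 and 0.40 for TGF-beta response, 0.37, 0.63 and 0.38 for mesenchymal and -0.25, -0.34 and -0.36 for lung lineage genes. For other lists, pairs of numbers give the genes higher and lower than the common RNA, in Control, Brg1i.1 and Brg1i.2 in turn. They were 2 and 7, 1 and 2, 0 and 3 for retinoid and glucocorticoid response genes. SWI/SNF subunits had 3 and 2, 0 and 1, 0 and 1, and p53 targets had 1 and 4, 0 and 1, 0 and 1. Neuroendocrine genes had 3 and 1, 0 and 2, 1 and 0, and fibroblast genes had 3 and 0, 1 and 0, 0 and 0. Most of these calls were thus in Control, as were those of immediate early genes (5 and 2, 2 and 2, 1 and 0) and of hypoxia genes (4 and 0, 0 and 1, 1 and 0).

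Among the genes ranked, Brg1i.2 and Brg1i.1 differed most in BATF, a transcription factor of lymphocytes, which was higher in Brg1i.2 by 3.96 on the log2 scale in the dye direction used here (SE 0.072, limma adjusted p = 7.14e-18), followed by CYB5R2 (2.58), INHBA (2.45), CASP1 (2.25) and SPANXA1 (2.22). MAF, a transcription factor of the AP-1 superfamily, had a difference of -3.69, being at 2.54 and -1.14 against Control in Brg1i.1 and Brg1i.2, and was well above background on 3 of 4 arrays of Brg1i.2. The next largest falls were in ACAA2 (-3.31), LY6D (-3.22), WWOX (-2.76) and CAPS (-2.71). SMARCA4 was 1.49 higher in Brg1i.2 than in Brg1i.1. In total 263 genes differed by at least 2-fold between these libraries, 107 higher and 156 lower in Brg1i.2, and the arrays did not overlap for 33.4% of genes, where chance gives 2.86%. The hairpin and the selection drug differed between them together. WWOX rested on 1 probe of 4 (the other three gave -0.415, -0.148 and 0.568 against Control in Brg1i.2), and the call of MAF in Brg1i.2 was lost with no background correction (-0.92). With the slide as a block 263 genes were called, and with Agilent's processed signals 619; in Cy3 alone limma called 0 (280 at an unadjusted p under 0.05).

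Against the common Cy3 RNA, the library labelled Control had, among the genes ranked, the highest levels of DLC1 (6.01), TCEAL9 (5.71), PRAME (5.13), ARHGEF40 (5.12) and KLRC4 (4.79), in log2. FGF13 (-6.94), AIM2 (-5.24), LIMCH1 (-4.93), HPGD (-4.88) and TCIM (-4.85) were furthest below it, and with the dyes as labelled these signs turn. Of 20472 genes, 2377 differed by at least 2-fold in Control (1131 higher, 1246 lower), against 599 in Brg1i.1 (245 and 354) and 600 in Brg1i.2 (225 and 375). The SD over genes of the log2 ratio to the common RNA was 0.722 in Control, 0.409 in Brg1i.1 and 0.421 in Brg1i.2. Across genes, which are not independent replicates, these ratios correlated with r = 0.602 between Control and Brg1i.1, 0.432 between Control and Brg1i.2 and 0.735 between Brg1i.1 and Brg1i.2. Of the 1210 shared calls against Control, Control itself was called in the opposite direction against the common RNA for 1039, neither Brg1i.1 nor Brg1i.2 was called for 985 and both were called in the same direction for 33. With the common RNA in place of Control, both libraries called 286 genes in the same direction, of which 33 were among the 1210. No dye swap was made, so a dye effect of a probe stays in all comparisons with the common RNA. The comparisons of Brg1i.1 and Brg1i.2 with the common RNA were chosen after the data were seen. With the slide as a block 2374 genes were called in Control, and at 1.5-fold 5310.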

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

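The tests of SMARCA4, of array position, of mixed RNA and of dye bias were chosen only after the result was seen, whereas the splits of the arrays were set before their results.

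SMARCA4 was lowest in the library labelled Control, at -2.43 in log2 against the common RNA. The dyes as the labels give them were excluded as the reason, since 70 genes differed by at least 2-fold between Brg1i.2 and Control in Cy3 against 3135 in Cy5, and so was 1 faulty probe, since all 3 SMARCA4 probes were lowest in Control. A candidate explanation that stays open, as a hypothesis, is that the dyes were exchanged and the arrays labelled Control and Brg1i.2 as well: SMARCA4 in the library labelled Brg1i.2 lay at -0.12 against the common RNA, within 1.5-fold of it, while the other two lay below. That value prompted the idea. Brg1i.1 would then differ from the other BRG1 hairpin line in 1475 genes (r = 0.602) and from the control line in 263 (r = 0.735). Under that exchange Brg1i.1 would also share its selection drug, G418, with the control line and not with the other hairpin line. These values therefore cannot decide. Right library labels with exchanged dyes and a Control line that had lost SMARCA4 stay open too, as does a wrong label of another kind, and no library was regrouped.

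The library labelled Control lay further from the common RNA than the other two, with 2377 genes at least 2-fold different against 599 in Brg1i.1 and 600 in Brg1i.2. An effect of array position on both dyes was excluded as the reason. Between Brg1i.1 and Control 52 genes differed by at least 2-fold in Cy3, which shared those positions, against 2590 in Cy5. Each library held the same position on every slide, so an effect of position on Cy5 alone cannot be told apart from the library. A mixture of RNA of other cells with H358 RNA of the parental profile was excluded for any H358 share above 6.25%, because 19 genes lay at least 16-fold below the common RNA, a bound worded after its value was seen. RNA of another line in place of this library stays open, as do a mixture with H358 RNA whose profile had changed and the biological differences of BRG1 depletion and of the selection of single lines, which were not tested.

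Interferon response genes lay below the common RNA in all 3 libraries, with 24, 19 and 21 of 38 genes lower in Control, Brg1i.1 and Brg1i.2 and medians of -1.12, -0.95 and -1.05. A dye bias of single probes was excluded as the reason, since random lists matched on intensity carry such bias and the list's median stood at percentile 0 among them in each library. A dye bias shared by these probes in particular stays open, because no dye swap was made. The 3 medians share 1 common RNA, so a high level of these genes in that RNA alone would put all 3 libraries below it. No second sample like the common RNA was measured, so no biological explanation was tested.

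Splits of the arrays excluded noise between technical arrays for each comparison between libraries, and say nothing of how far single lines differ from each other by chance. Of the 35 splits of the 8 arrays of Brg1i.1 and Control into 4 and 4, 1, the real one, called as many as 1475 genes, and the highest other called 1. For Brg1i.2 against Control it was again 1 of 35, with 1965 genes and a highest other of 1, and for Brg1i.2 against Brg1i.1 it was 1 of 35, with 263 genes and a highest other of 0.

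In 23 of 387 groups of 4 arrays (the log2 ratios of 1 named gene in 1 library) the highest or lowest array stood apart from the others. Chance gives about 1 in 20 groups, which is close to this share. The gap to the nearest array as a share of the whole range was the measure. It can be high where all arrays lie close together, as for SPANXA1 in Brg1i.1 (-0.194 to -0.0763). In the Control library these were CXCL8 (0.956), CCN2 (0.931), FAS (0.838), MX1 (0.875) and BAMBI (0.833). In Brg1i.1 they were CEMIP (0.952), ZNF219 (0.839), SPANXA1 (0.972), KRT19 (0.961), TYMS (0.849), PHLDA3 (0.965), LSS (0.844), BAMBI (0.835), LAMA3 (0.857) and CRYGC (0.898), and in Brg1i.2 KCNK1 (0.881), EPCAM (0.853), CCN1 (0.92), FAS (0.862), SAMD9L (0.919), HLA-DPA1 (0.895), SLC7A11 (0.893) and LEF1 (0.84). The widest was CXCL8 in Control, whose 4 arrays ran from -2.96 to -1.49 around a median of -2.9.

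Of 130 named genes, 23 differed between Brg1i.2 and Brg1i.1 by more than 2-fold in limma's treat test of the difference itself (adjusted p under 0.05). The log2 difference of Brg1i.2 from Brg1i.1 was positive for BATF (3.96), CYB5R2 (2.58), INHBA (2.45), CASP1 (2.25), SPANXA1 (2.22), SPANXB1 (2.19), SPANXD (2.05), ANGPTL2 (1.94), GNG11 (1.79), SMARCA4 (1.49), AIM2 (1.42), AKR1C1 (1.34) and IL1B (1.28). It was negative for MAF (-3.69), ACAA2 (-3.31), LY6D (-3.22), WWOX (-2.76), CAPS (-2.71), ARHGEF40 (-2.60), TTC7B (-2.28), PRAME (-2.18), PNMA2 (-1.75) and AMY1C (-1.69). The share of 23 in 130 was set in part by how genes were named. BATF and MAF, among others, were named for having the largest differences between these libraries. Over all 20472 genes, limma's treat test against 2-fold called 117 between Brg1i.2 and Brg1i.1.

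Outside the comparisons, 20 probes that were not well above background in Cy3 on any array were so in Cy5 on all 4 arrays of Brg1i.1 or of Brg1i.2 and on no Control array. The reverse, on all 4 Control arrays and on no array of the other two, held for 269 probes.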

How the results depend on the processing

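Cy5 alone, the filter on Cy5 and the common RNA in place of Control were added after the data were seen. Numbers of called genes are given for Brg1i.1 against Control, Brg1i.2 against Control, both in 1 direction, and Brg1i.2 against Brg1i.1, which were 1475, 1965, 1210 and 263 as reported. They were 1365 to 1851, 1819 to 2392, 1111 to 1499 and 225 to 370 with a normexp offset of 10, no background correction, median centring, Aquantile (which leaves the ratios as they are), the authors' matrix values, 3 other filters and the mean over probes. Leaving out 1 array at a time gave 1475 to 1508, 1950 to 1997, 1197 to 1232 and 247 to 271 genes, 2328 to 2393 for Control against the common RNA, and log2 differences of SMARCA4 of 0.78 to 0.85 in Brg1i.1 and 2.27 to 2.34 in Brg1i.2. Agilent's processed signals gave 2467, 2994, 1959 and 619, of which 1459, 1958 and 1198 of the first 3 were among the reported genes, and Cy5 alone gave 2544, 3100, 2052 and 662, of which 1435, 1918 and 1184 were; the cause was not tested. At 1.5-fold the numbers were 3928, 4554, 3128 and 980, with 5310 for Control against the common RNA and SMARCA4 in Brg1i.1 past the threshold at 0.82, and limma's treat test against 2-fold gave 914, 1304, 753 and 117, by the construction of these thresholds. With the common RNA in place of Control, 599, 600 and 286 genes were called, of which 73, 145 and 33 were called in the same direction in the reported comparison. Control against the common RNA had 1811 to 3483 genes under the alternatives other than 1.5-fold and single arrays left out, and single-channel values gave no such comparison.

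Cy3 alone gave 49, 65 and 47 genes, all lower and 45, 61 and 43 of them among the reported, and 0 between Brg1i.2 and Brg1i.1 in limma (280 at an unadjusted p under 0.05), with SMARCA4 at -0.037 in Brg1i.2. That channel held a nearly constant RNA, and why many signs turned there was not tested. Among the named genes, with log2 differences from Control in Brg1i.1 and then in Brg1i.2, SMARCA2 (-0.060 and -0.10), FGF13 (-0.013 and -0.066), TCIM (-0.091 and -0.11), LIMCH1 (-0.049 and -0.034), NKX2-1 (-0.034 and -0.030), AMY1C (-0.090 and -0.092), SPANXB1 (-0.041 and -0.29) and SPANXA1 (-0.14 and -0.56) turned below 0 in both libraries. SPANXD (-0.012 and -0.13), SYK (-0.032 and -0.084), CXCL8 (-0.35 and -0.12), EPCAM (-0.31 and -0.18), GRHL2 (-0.12 and -0.10), KRT19 (-0.59 and -0.61), HOPX (-0.025 and -0.029) and FAP (-0.12 and -0.11) turned below 0 in both libraries. FAS (-0.012 and -0.065), MX2 (-0.022 and -0.018), IL1B (-0.12 and -0.12), AREG (-0.16 and -0.21), EREG (-0.017 and -0.076), SLC7A11 (-0.17 and -0.086), VLDLR (-0.032 and -0.047) and LAMA3 (-0.014 and -0.023) turned below 0 in both libraries. MCTP2 (-0.090 and -0.15) turned below 0 in both libraries. TFPI2 (0.21 and 0.15), ACAA2 (0.10 and 0.036), SMARCA1 (0.013 and 0.034), TYMS (0.17 and 0.30), IFIT1 (0.077 and 0.063), ASNS (0.18 and 0.20), LSS (0.17 and 0.16) and UQCRC2 (0.14 and 0.13) turned above 0 in both. KRT8 (-0.047), CDH11 (-0.020), JUNB (-0.11) and RARB (-0.022) turned below 0 in Brg1i.1 alone. TTC7B (0.028), ADM (0.034), TM7SF2 (0.044) and LEF1 (0.039) turned above 0 in Brg1i.1 alone. SLAMF7 (-0.023), AIM2 (-0.015), DAPP1 (-0.042), KCNK1 (-0.045), ZBED2 (-0.0030), CAPS (-0.024), LCK (-0.0079), HPGD (-0.018), TEK (-0.16), PECAM1 (-0.13), ICAM1 (-0.041), CTSS (-0.026) and ME1 (-0.0021) turned below 0 in Brg1i.2 alone. MMP7 (-0.0075), MMP1 (-0.015), BIK (-0.024), CASP1 (-0.038) and BATF (-0.0085) turned below 0 in Brg1i.2 alone. MX1 (0.040), BIRC3 (0.0074), MAF (0.027) and WWOX (0.030) turned above 0 in Brg1i.2 alone. List medians that turned in Cy3 alone were those of other remodellers (0.010), endothelial (-0.034), MAPK output (-0.016) and integrin, laminin and metalloprotease genes (-0.0017) in Brg1i.2, of TGF-beta response genes in Brg1i.1 (-0.047), and of cholesterol synthesis (0.044 and 0.056) and ribosomal protein genes (0.095 and 0.19) in both. Outside Cy3 alone, 1 named result turned, CYB5R2 in Brg1i.1 without Control replicate 1 (0.016, from -0.042). Over all alternatives, 6866 results of single named genes kept direction and side of the threshold, 190 lost the call, 49 gained it and 97 turned. Cy3 alone, which held the nearly constant RNA, gave 132 of the lost calls and 96 of those that turned. The 6866 include 258 each for Aquantile and either block, which could change little or nothing. For medians of lists, 756 moved by less than their spread between slides, 163 by more and 9 turned, where only medians outside the central range of random lists could turn (those nearer 0 that changed sign are given in the report), and with 1 array left out 656 and 40 moved by less and by more. The 756 include 58 each for Aquantile, the 1.5-fold threshold, the treat test and either block. These settings leave a median as it is or can hardly move it, so that part of the 756 says nothing of robustness.

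The comparison with each line as 1 replicate called 1467 genes as reported. It gave 966 genes with no background correction, 578 with the processed signals, 760 with Cy5 alone, 11 with Cy3 alone, 104 with no filter on dim probes and 0 in limma (867 at an unadjusted p under 0.05) with the parental RNA as a second line. Leaving out 1 array at a time gave 936 to 1767, the lowest without Brg1i.1 replicate 1 and no other over 1.5 times away. The parental RNA differed from Control by at least 2-fold in 2377 genes, which widened the spread between these as 2 lines of 1 group; for the others the cause was not tested.

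With the replicate number of the titles as a block, 1474, 1966, 1210 and 263 genes were called and 2375 for Control against the common RNA, and with the slide as a block 1474, 1966, 1209 and 263 and 2374. Arrays with the same title number had deviations that correlated with r of -0.28 to 0.45 over 12 pairs, so the numbers do not pair the arrays, whereas arrays of 1 slide correlated with 0.30 to 0.54. Signal over background limited the genes that were dim in a library, which have no exact difference there, and 1 line per label limited every comparison to the spread between technical arrays.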

Other observations

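Between the libraries labelled Brg1i.2 and Brg1i.1, genes of antigen presentation and of MAPK signalling lay higher in Brg1i.2 by their medians, by small amounts. Over all 20472 genes, 9360 had an unadjusted p under 0.05 in limma between these libraries, in either direction. Of 17 MHC class I and antigen processing genes, limma called 0 at 2-fold (15 at an unadjusted p under 0.05), with a median log2 difference of 0.44. Of 23 MAPK output genes, 2 were higher, the phosphatase gene DUSP6 and the transcription factor gene EGR1, and the median was 0.37. MHC class II genes had a median of 0.31 with 0 called in limma (7 at an unadjusted p under 0.05), and NF-kB and cytokine genes one of 0.24 with 1 higher, IL1B. These 4 medians stood at percentile 100 of 10000 random lists matched on intensity. They were 0.34 to 0.49, 0.30 to 0.42, 0.18 to 0.28 and 0.13 to 0.24 within the 4 slides, and 0.37 to 0.55, 0.31 to 0.39, 0.15 to 0.47 and 0.13 to 0.27 over 10 ways of processing. Lower in Brg1i.2 by their medians were ATPases of other chromatin remodellers (-0.26, percentile 0.01, -0.33 to -0.25 over those ways) and genes of the unfolded protein and ATF4 responses (-0.19, percentile 0.01, -0.20 to -0.078), with 0 called in limma in each list (14 of 19 and 21 of 30 at an unadjusted p under 0.05). The hairpin, its selection drug and the line differed together between these libraries, these lists, DUSP6 and EGR1 were picked for this account after their values were seen, and with the dyes as labelled every sign turns.

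Some probes were above background in the library labelled Control and dark in the common RNA, and so were left out of the tests. Some of their genes, such as LEF1, SORBS2 and TTC7B, were tested through another probe. In Cy5, 426 probes that were not well above background on any Cy3 array were so on all 4 Control arrays, against 55 for Brg1i.1 and 65 for Brg1i.2, and 269 of the 426 on no array of the other two. PPP4R4, a regulatory subunit of protein phosphatase 4, had a mean processed Cy5 signal of 340.9 against 2.06 and 3.44 in Control, Brg1i.1 and Brg1i.2, and its other probe 289.7 against 2.87 and 2.6. COL3A1, a fibrillar collagen gene of connective tissue, stood at 192.7 against 2.68 and 3.31, but another probe of it at only 19.51 against 3.32 and 2.33. NLRP2 stood at 193.5 against 5.59 and 3.57, HTRA1, a secreted serine protease, at 148.6 against 6.94 and 8.81, and SLC1A3, a glutamate transporter, at 105.9 against 2.38 and 4.4. All of these were well above background on 4 of 4 Control arrays, and on none of Brg1i.1 and Brg1i.2 except HTRA1 on 1 array of Brg1i.2. PPP4R4, COL3A1, NLRP2, HTRA1 and SLC1A3 were chosen after their values were seen, and the levels come from 1 channel without a test.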
